A study of Mus musculus with 6 samples.

How the data were processed

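Per the series' design text, RNA was isolated with a Qiagen RNeasy kit and made into libraries with an Illumina TruSeq RNA kit. The 6 libraries came from MIN6 cells, a mouse insulinoma line used as a model of pancreatic beta cells. Per the labels, 3 libraries were from cells given a control ASO and 3 from cells given an ASO against Paupar, ASO being the usual abbreviation of antisense oligonucleotide. Paupar is a long noncoding RNA transcribed next to the gene of the transcription factor PAX6.

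The authors deposited 1 table per library with a raw read count for each of 23284 gene symbols, with no normalization and no rows for unassigned reads. Per the submitters' processing notes, CASAVA 1.8.2, HISAT2, HTSeq and DESeq2 were used with the mouse genome build mm9; their roles, the strand setting and the gene annotation are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as Ins1 and Ins2 or genes with many pseudogenes, may therefore be divided differently from their true origin. None of the gene symbols matched Paupar, so the knockdown itself was not measured. Library totals were 16973622 to 28693863 counts.

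The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr (minimum count 10, smallest group 3), which left 13039 genes. Libraries were scaled by TMM, and Paupar KD was compared with control KD by the quasi-likelihood test with robust estimation and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are given as CPM, the deposited counts scaled to a common library total with the TMM factors, as mean ± SD over 3 libraries. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. No batch or date is given in the labels.

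Gene lists were written before the data were examined: 21 lists with 455 entries, of which 365 were tested. They were tested with camera (edgeR and limma 3.58.1) at a preset correlation between genes of 0.01, then with an estimated correlation and with fry. Members were counted after adjustment over all genes and after adjustment over the list alone. Genes named in the text follow a rule that was also fixed beforehand: Paupar, Pax6, Ins1, Ins2 and Gcg, then up to 8 genes per direction with the largest change among those past the threshold with a mean of at least 5 CPM and no overlap between groups, then up to 4 members per list past the threshold or, where none passed, the member with the smallest p. Other genes were chosen after their values were seen: list members that passed only over the list alone, and Elp4, Immp1l, Pax6os1, Pdx1, Nkx6-1, Mafa, Pkm2, Ldha, Bnip3, Slc16a3, Txnip, Rn45s, Neat1 and Malat1. The values of 1 gene that the rule names, in the cholesterol list, are not reported here.

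No pair of libraries agreed within sampling noise: a chi-square per gene, 1 if only sampling differed, was 3.48 to 8.48 between controls. Alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom, no robust estimation, a replicate block, other thresholds and leaving out each library; limma-voom with sample quality weights was added after the data were seen. On simulated counts with the fitted means and trended dispersions of this comparison (13039 genes), edgeR called 36 of 67 genes changed by 1.5-fold, 58 of 67 changed by 2-fold and 64 of 66 changed by 4-fold, with 9 false calls. That simulation gave both groups the same dispersion, while the Paupar KD libraries varied more than the controls, so its shares do not carry over to these data directly.

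Gene positions and 3' UTR sequences are from the GENCODE M1 annotation of the NCBIM37 assembly, which is the assembly called mm9. For each gene symbol the longest annotated 3' UTR was used, which was found for 93.8% of the tested genes. Every word of 6 or 7 bases present in the 3' UTRs of at least 30 tested genes was compared with the change of those genes. Gene changes were turned into rank-normal scores and corrected for the length and GC content of the 3' UTR. The z of a word is the mean score of its genes divided by the standard error of a mean over equally many random genes. The word search was tested on simulated scores, where the word with a planted effect ranked highest.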

Results

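Messenger RNA was measured by sequencing in 6 libraries of MIN6 mouse beta cells, 3 after control knockdown (KD) and 3 after knockdown of the long noncoding RNA Paupar. The design asks which genes respond when Paupar is reduced. Total counts were 22463557, 23624880 and 28693863 in control KD replicates 1 to 3 and 16973622, 20302121 and 23434166 in Paupar KD replicates 1 to 3. No gene symbol in the counts matched Paupar itself, so they give no direct check of the knockdown.

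The Paupar KD libraries were far less alike than the controls. The biological coefficient of variation was 4.97% among the 3 controls and 18.7% among the 3 Paupar KD libraries. Paupar KD replicate 1 stood farthest from the rest, with Pearson correlations of log2 CPM across genes of 0.975 to 0.976 with the controls and of 0.973 with Paupar KD replicate 3. Control pairs reached 0.996. The 1st principal component held 53.3% of the variance and placed Paupar KD replicate 1 at 45.0, replicate 2 at 8.89 and replicate 3 at -11.5, with the controls at -14.8 to -12.7. On the 2nd, with 21.7%, replicate 3 lay farthest from the controls, at -26.8 against 9.76 to 11.02, with replicate 1 at 4.72 and replicate 2 at -9.09.

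In Paupar KD, 5 genes rose and 1 fell out of 13039 tested. Ryk, which encodes a receptor-like kinase that binds Wnt proteins, rose 2.29-fold, from 47.0 ± 1.26 to 108 ± 5.94 CPM (SD, n = 3 per group; log2 fold change 1.20 ± 0.08 SE; edgeR adjusted p = 0.00615). Srp14, a subunit of the signal recognition particle, rose 2.22-fold, from 57.7 ± 3.08 to 128 ± 22.5 CPM (edgeR adjusted p = 0.0465). Eif2s3x, which encodes the gamma subunit of translation initiation factor eIF2, rose 2.06-fold, from 13.4 ± 0.30 to 27.5 ± 1.79 CPM (edgeR adjusted p = 0.0355). Cdc42se2, which encodes a small effector of the GTPase CDC42, rose 2.03-fold, from 105 ± 4.36 to 213 ± 31.5 CPM, and the RNA-binding protein gene Rbm18 rose 2.01-fold, from 18.97 ± 0.65 to 38.0 ± 4.15 CPM (edgeR adjusted p = 0.0465 for each). Ranbp6, of the importin family of nuclear transport receptors, fell to 0.58 of its control level, from 65.9 ± 3.53 to 38.2 ± 2.37 CPM (edgeR adjusted p = 0.0465). The 3 values of one group lay apart from the 3 of the other for each of these 6 genes.

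**Figure D1:**
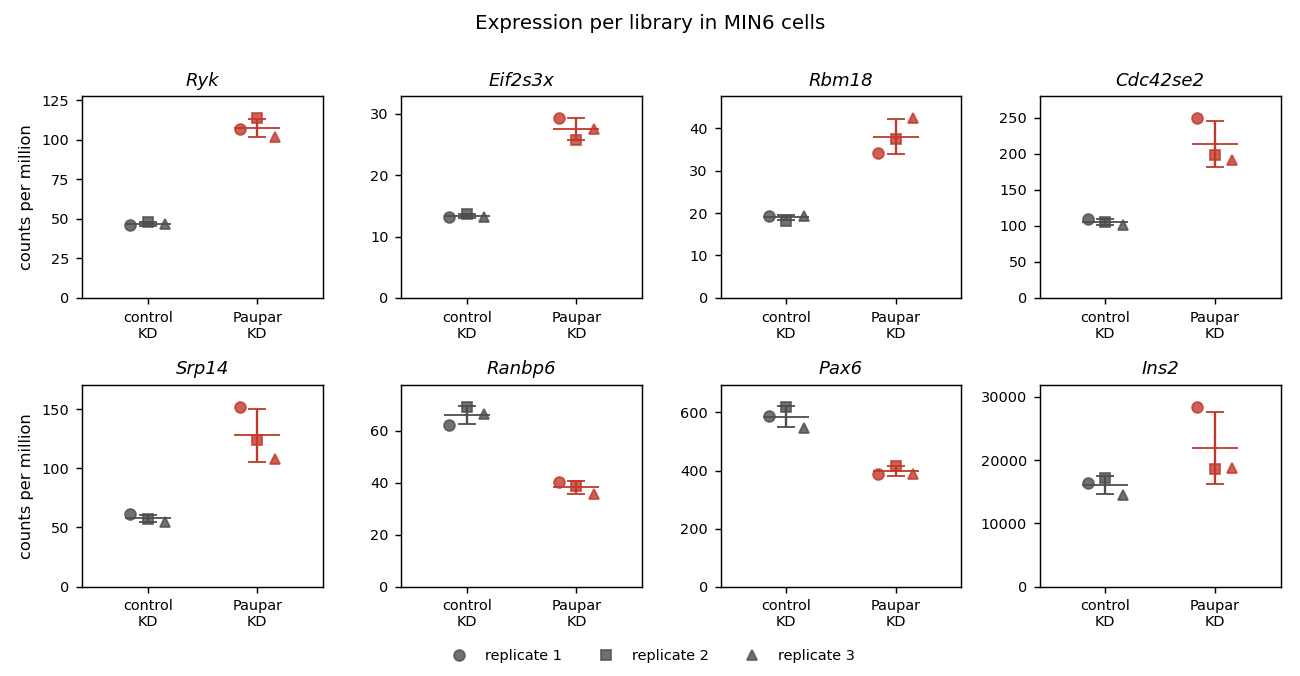
CPM in each of the 6 libraries for the 6 genes that passed the test and for Pax6 and Ins2, which did not. Points are libraries, marked by replicate number, and the horizontal bars with whiskers are the mean ± SD of 3 libraries; Ryk lay at 45.8 to 48.3 CPM in the controls and at 102 to 114 CPM in Paupar KD.

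These genes lie at separate places in the mm9 assembly: Ryk on chromosome 9 (102737250 to 102810637), Eif2s3x on chromosome X (91434046 to 91458201), Cdc42se2 on chromosome 11 (54530958 to 54601177), Ranbp6 on chromosome 19 (29882598 to 29887464), and Rbm18 (35971599 to 35992293) and Srp14 (118301586 to 118305447) on chromosome 2. In their annotated 3' UTRs, Ryk, Eif2s3x and Cdc42se2 each contain the word GACGTA once, and Rbm18 and Srp14 each contain GACAGTA once. The Ryk site is at 102809431 to 102809436 of chromosome 9, in TTTTAACGATGACGTAATAACGCAGA. The Ranbp6 3' UTR contains GATGCAA once, at 29883801 to 29883807 of chromosome 19, and ATTACAA at 2 places. ATTACAA is also present in Ryk, and GTCTTCC in Eif2s3x and Rbm18; these 3 genes rose, although genes with either word had lower scores over the comparison (z = -5.20 and -6.05, against up to 5.77 in size for any word between 2 controls).

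The count of responding genes depended on the test and on single libraries. At an unadjusted p under 0.05, edgeR gave 1256 higher and 1058 lower genes, 2314 in all. Chance gives 652 if all libraries vary alike, which they did not, so 652 is not an exact reference. Other splits of the same libraries into 3 and 3 gave 75 to 686 such genes. DESeq2 called 262 higher and 220 lower genes, including the same 6. Without Paupar KD replicate 1, edgeR called 123 higher and 128 lower genes, and without Paupar KD replicate 3 it called 611 and 745, each time including the same 6. Without Paupar KD replicate 2, or without any single control library, it called 0 genes in either direction, with 1130 to 2062 genes at an unadjusted p under 0.05. Values of the groups did not overlap for 1790 genes that were higher and 1738 that were lower, 27.1% of the genes. Chance gives 10% if all libraries vary alike. The Paupar KD libraries varied more than the controls, so that 10% is not a fair reference and the excess does not measure a group effect.

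Pax6, the transcription factor gene beside Paupar (chromosome 2, 105509053 to 105543317), was at 585 ± 36.4 CPM in control KD and at 398 ± 16.7 CPM in Paupar KD, 0.68 of the control level. All 3 Paupar KD libraries, at 387 to 417 CPM, lay below the 3 controls, at 547 to 620 CPM. The difference did not pass over all genes (log2 fold change -0.56 ± 0.09 SE, edgeR adjusted p = 0.0694) and passed when adjusted over the list alone, among the genes of the targeted locus (edgeR adjusted p = 8.09e-04). Of the 4 tested genes of that list, 0 passed over all genes and 2 were lower when adjusted over the list alone: Pax6, and Rcn1 at 2.96 ± 0.19 and 1.805 ± 0.48 CPM (edgeR adjusted p = 0.0292). The other 2 tested members were Elp4 and Immp1l: Elp4 was at 52.7 ± 1.92 and 51.9 ± 6.07 CPM, and Immp1l at 17.8 ± 2.88 and 19.5 ± 2.65 CPM. Pax6os1, which is outside the list and overlaps the start of Pax6 on the opposite strand, was at 10.8 ± 0.86 and 6.41 ± 0.56 CPM, 0.59 of the control level with no overlap between groups, and did not pass over all genes (edgeR adjusted p = 0.0856). With the strand setting unknown, reads of Pax6 and Pax6os1 in their shared part cannot be told apart. As a set, the locus gave camera adjusted p = 0.148, and adjusted p = 0.683 with an estimated correlation. Without Paupar KD replicate 2 it was called down at the preset correlation (camera adjusted p = 0.0236) and not with an estimated correlation (adjusted p = 0.803). Leaving out any other single library gave no call of the locus at the preset correlation (camera adjusted p = 0.0528 to 0.394). Limma's fry gave adjusted p = 0.425 for change in 1 direction and 0.0242 for change in either direction.

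Hormone genes did not pass the test. Ins2 was at 15995 ± 1422 CPM in control KD and 21916 ± 5659 CPM in Paupar KD (edgeR adjusted p = 0.253), and Paupar KD replicate 1 alone was at 28450 CPM against 18601 and 18696 CPM in replicates 2 and 3. Ins1 was at 6340.1 ± 373 and 8673 ± 4927 CPM (edgeR adjusted p = 0.490), with 14318 CPM in Paupar KD replicate 1 and 5239 to 6461 CPM in the others. Gcg, the glucagon gene, was at 71.1 ± 4.83 and 76.4 ± 43.0 CPM (edgeR adjusted p = 0.899). Its level was 124 CPM in Paupar KD replicate 1 and 64.0 and 40.9 CPM in replicates 2 and 3, against 66.6 to 76.2 CPM in the controls. Without Paupar KD replicate 1 the log2 fold change of Gcg was -0.45 (edgeR adjusted p = 0.219). Ins1 and Ins2 share much of their sequence, so reads could be divided between them. The 4 tested hormone genes gave 0 calls and camera adjusted p = 0.282.

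Among 24 beta cell identity genes, 0 passed over all genes and 1 was lower when adjusted over the list alone. That gene was Rfx6, a transcription factor of islet development, at 99.1 ± 3.93 and 69.9 ± 5.47 CPM, 0.71 of the control level (edgeR adjusted p = 0.0856 over all genes and 0.0114 over the list). Pdx1 stood at 355 ± 29.4 and 378 ± 25.6 CPM, Nkx6-1 at 306 ± 33.6 and 346 ± 41.8 CPM, and Mafa at 211 ± 33.3 and 384 ± 249 CPM, with 670.1 CPM in Paupar KD replicate 1 alone. The list gave camera adjusted p = 0.282; its direction was down with a mean log2 fold change of -0.07 and a median of 0.03. Without Paupar KD replicate 1 this list was called down at the preset correlation (camera adjusted p = 0.00175) and not with an estimated correlation (adjusted p = 0.467; 0.699 with all 6 libraries). Limma's fry gave adjusted p = 0.547 for change in 1 direction and 0.0380 for change in either direction. Of 17 genes that depend on PAX6 in endocrine cells, 13 had positive and 4 negative log2 fold changes and 0 passed either way (camera adjusted p = 0.630). Their median log2 differences from the control mean were 0.37, -0.01 and -0.10 in Paupar KD replicates 1 to 3. Without Paupar KD replicate 1 the direction of the PAX6-dependent list turned to down, without a call (camera adjusted p = 0.0706, and 0.797 with an estimated correlation). Gipr, the GIP receptor gene, had the smallest p of these 17 genes, at 55.8 ± 3.79 and 34.6 ± 12.3 CPM (edgeR adjusted p = 0.218). Of 9 alpha cell markers, 0 passed over all genes, and when adjusted over the list alone Etv1 was higher (87.9 ± 9.82 and 122 ± 18.2 CPM) and Dpp4 lower (114 ± 3.92 and 91.7 ± 3.71 CPM), each at an edgeR adjusted p of 0.0280; the list gave camera adjusted p = 0.630.

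Genes of energy metabolism gave the 2 lists called as sets. Of 16 glycolysis genes, 15 had negative log2 fold changes, with a median of -0.44, and 36 of 36 nuclear genes of oxidative phosphorylation had positive ones, with a median of 0.17 (camera adjusted p = 2.25e-04 for each). With an estimated correlation neither list was called (adjusted p = 0.683 for each). No single member passed over all genes; 1 glycolysis gene, Gapdh, was lower when adjusted over the list alone, at 9.77 ± 0.83 and 5.13 ± 1.32 CPM (edgeR adjusted p = 0.0185), a level that is uncertain because the gene has many pseudogenes and how reads were divided among them was not tested. Pkm2, the main pyruvate kinase gene, was at 2369 ± 92.9 and 1863 ± 308 CPM, and Ndufs1, of complex I, at 175 ± 5.28 and 224 ± 2.71 CPM (edgeR adjusted p = 0.233 and 0.128). The change lay mostly in Paupar KD replicate 1: the median log2 difference from the control mean was -1.11, -0.48 and 0.08 for glycolysis in Paupar KD replicates 1 to 3, and 0.35, 0.08 and 0.04 for oxidative phosphorylation. Gapdh and Ndufs1 did not follow their lists in this. In Paupar KD replicates 1 to 3 Gapdh was at 6.61, 4.70 and 4.08 CPM and Ndufs1 at 227, 223 and 221 CPM. Without Paupar KD replicate 1 the oxidative phosphorylation list was no longer called (camera adjusted p = 0.0575), while glycolysis was still called down at the preset correlation (0.00839) and not with an estimated correlation (adjusted p = 0.797).

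**Figure D2:**
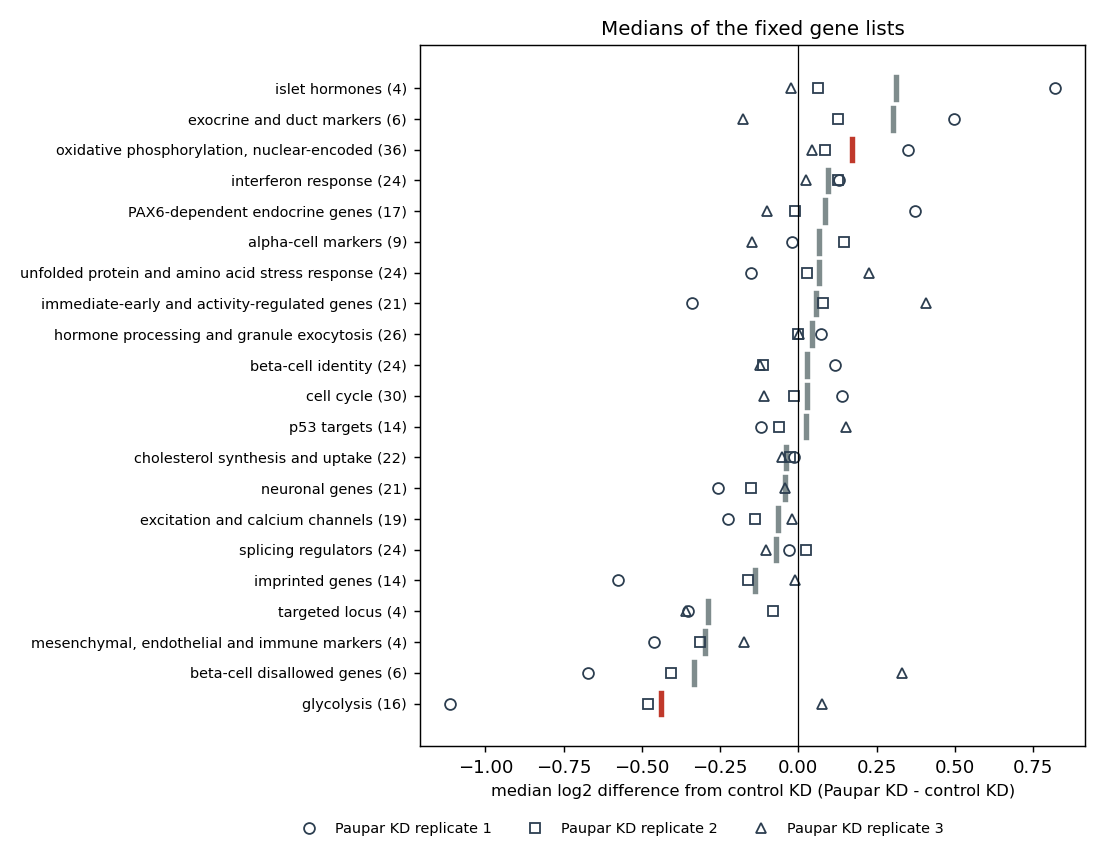
Median log2 difference between Paupar KD and control KD for each fixed gene list, with the number of tested genes in parentheses. Thick bars are medians of the fitted log2 fold changes, red where camera at the preset correlation called the list, and open symbols are the medians of single Paupar KD libraries against the mean of the 3 controls; for glycolysis these run from -1.11 in replicate 1 to 0.08 in replicate 3.

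Stress and signalling lists were not called as sets at the preset correlation. Of 24 genes of the unfolded protein and amino acid stress response, 13 had positive and 11 negative log2 fold changes. When adjusted over the list alone 4 were higher, and 0 passed over all genes. All 4 act in protein folding in the endoplasmic reticulum or its stress response: Sdf2l1 (120 ± 4.33 and 177 ± 19.9 CPM), Manf (278 ± 12.6 and 397 ± 45.3 CPM), Dnajc3 (198 ± 6.01 and 250 ± 13.9 CPM) and Creld2 (114 ± 3.31 and 167 ± 39.5 CPM). Of 21 immediate-early and activity-regulated genes, 11 had positive and 10 negative log2 fold changes, and 0 passed over all genes. Over the list alone 4 were higher: Dusp6, an ERK phosphatase gene (4.82 ± 0.77 and 13.3 ± 4.51 CPM, 2.74-fold), Nr4a2 (12.9 ± 0.93 and 22.5 ± 4.56 CPM), Crem (4.90 ± 0.56 and 7.62 ± 1.16 CPM) and Sik1 (15.5 ± 3.27 and 22.8 ± 1.97 CPM). Both lists gave camera adjusted p = 0.277, and both were called up without Paupar KD replicate 1 at the preset correlation (camera adjusted p = 0.00212 and 0.00271). Without Paupar KD replicate 3 neither was called (camera adjusted p = 0.961 and 0.972). In Paupar KD replicates 1 to 3 the median log2 differences from the control mean were -0.15, 0.03 and 0.23 for the stress list. For the immediate-early list they were -0.34, 0.08 and 0.41. With an estimated correlation neither list was called, with all 6 libraries (adjusted p = 0.683 for each) or without Paupar KD replicate 1 (adjusted p = 0.541 and 0.797). Of 24 interferon response genes 1 was lower over the list alone, Mx1, at 102 ± 4.98 and 65.7 ± 8.02 CPM (edgeR adjusted p = 0.0771 over all genes). As a set, interferon genes gave camera adjusted p = 0.630, and limma's fry gave adjusted p = 0.856 for change in 1 direction and 0.0161 for change in either direction. Of 14 p53 targets 0 passed either way; Perp was at 63.1 ± 1.74 and 50.4 ± 5.13 CPM, and the list gave camera adjusted p = 0.685 in the downward direction with a median log2 fold change of 0.03.

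The secretion, channel, cell cycle and splicing lists held 0 calls over all genes and 0 over the list alone. Of 26 genes of hormone processing and exocytosis the smallest p was that of Rab3a, a granule GTPase gene, at 55.0 ± 3.91 and 87.5 ± 20.2 CPM (camera adjusted p = 0.433). Of 19 excitation and calcium channel genes it was that of Cacnb2, at 43.9 ± 1.03 and 33.7 ± 3.84 CPM (camera adjusted p = 0.282). Of 30 cell cycle genes it was that of Mki67, a proliferation marker, at 752 ± 67.1 and 469 ± 112 CPM (edgeR adjusted p = 0.149; camera adjusted p = 0.708). Of 24 splicing regulators it was that of Ptbp2, at 53.7 ± 1.15 and 75.0 ± 17.7 CPM (camera adjusted p = 0.630). Of 22 cholesterol genes 0 passed over all genes (camera adjusted p = 0.357). Of 14 imprinted genes, Peg3 (540.3 ± 37.1 and 388 ± 63.2 CPM) and its neighbour Zim1 (13.7 ± 1.72 and 9.41 ± 1.26 CPM) were lower and Nap1l5 (49.0 ± 1.28 and 64.7 ± 8.10 CPM) higher over the list alone, with 0 over all genes (camera adjusted p = 0.307).

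Markers of other cell types stayed low or did not pass. Of 20 mesenchymal, endothelial and immune markers only 4 had enough counts to be tested; Cd68, a macrophage marker, was lower over the list alone at 2.46 ± 0.02 and 1.10 ± 0.35 CPM (camera adjusted p = 0.282). Of 21 exocrine and duct markers 6 were tested and 0 passed either way, with Cela1 at 1.34 ± 0.25 and 0.78 ± 0.18 CPM (camera adjusted p = 0.459). Of 21 tested neuronal genes 0 passed either way, with Th, the tyrosine hydroxylase gene, at 367 ± 9.07 and 283 ± 30.8 CPM (camera adjusted p = 0.282). Of 20 genes that beta cells normally keep low 6 were tested and 0 passed either way; Smad3 was at 18.3 ± 0.45 and 14.4 ± 3.81 CPM (camera adjusted p = 0.433), and Ldha ran from 66.3 CPM in Paupar KD replicate 1 to 823 CPM in replicate 3.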

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

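Limma-voom with quality weights, and an estimated correlation with a library left out, were tried only after the data were seen. Against 5 higher and 1 lower genes, the counts were 3 and 0 with upper-quartile factors, 36 and 24 without a low-count filter, 2 and 0 with a mean CPM of at least 1, 262 and 220 with DESeq2, 745 and 950 with limma-voom and quality weights, and 1 and 0 at an adjusted p under 0.01; the cause was not tested. Leaving out 1 library gave from 0 to 611 higher and from 0 to 745 lower genes: 0 in both directions without control KD replicate 1, 2 or 3 or Paupar KD replicate 2, 123 and 128 without Paupar KD replicate 1, and 611 and 745 without Paupar KD replicate 3. With a replicate block, edgeR called 1 higher gene, Ryk, and 0 lower. Whether the numbers pair the libraries could not be told. Deviations from the group means of same-numbered libraries correlated at 0.07, -0.01 and 0.01. Paupar KD replicate 1 correlated best with the control of its own number, and replicates 2 and 3 each with a control of another number. The Paupar KD libraries varied far more than the controls, so a weak shared effect could be hidden in these correlations. RLE factors, library size alone, no robust estimation and limma-voom each called the same 6 genes, and a fold change over 1.5 removed none of them. Of the 29 named genes, 27 kept their direction in 16 alternatives, and Ins1 and Gcg changed direction in at least 1; these 2 were never called. Pax6 stayed lower, at log2 fold changes of -0.60 to -0.52, and passed the threshold in 5 of 16 alternatives (adjusted p = 4.34e-06 to 0.493). Of the gene lists, 2 were called at the preset correlation, 0 with an estimated correlation and 0 by fry for change in 1 direction; fry's test for change in either direction, which is another question, called 3. With 1 library left out, 2 to 4 were called at the preset correlation, 4 of them without Paupar KD replicate 1, and 0 with an estimated correlation; the block changed no list call. Thinning every library to 16973622 counts gave 5 higher and 1 lower genes. Of 23284 gene symbols 13039 were tested, and how far depth limited that number was not examined.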

Other observations

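The word search and the list of hypoxia-regulated genes were added after the data were seen, and the tests of GACGTA, GATGCAA and ATTACAA in disjoint pairs of libraries were chosen after their results were seen. Genes that respond to low oxygen set Paupar KD replicate 1 apart from replicate 3. Ldha was at 66.3, 407 and 823 CPM in Paupar KD replicates 1 to 3 against 632 ± 47.1 CPM in the controls (SD, n = 3), Bnip3 at 70.8, 308 and 509 against 475 ± 42.8, and the lactate transporter gene Slc16a3 at 88.6, 266 and 513 against 459 ± 24.7. Txnip, a glucose-responsive gene, was at 162, 40.1 and 25.0 CPM against 29.5 ± 1.005. None of the 4 passed the edgeR test (adjusted p = 0.286 to 0.691).

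Some abundant noncoding transcripts differed in all 3 Paupar KD libraries without passing the test. Rn45s, the ribosomal RNA precursor, a many-copy gene whose reads cannot be placed uniquely, was at 7059, 6437 and 8202 CPM against 1489 to 3234 CPM in the controls (2.76-fold, edgeR adjusted p = 0.0979). Neat1 was at 1025, 1367 and 690.5 CPM against 1735 ± 79.9 (edgeR adjusted p = 0.169), and Malat1 at 295, 526 and 317 CPM against 612 ± 41.5 (edgeR adjusted p = 0.184).

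Short words in 3' UTRs tracked the comparison. Over 12236 genes the word with the largest z was GACGTA, carried by 585 genes (z = 14.0; permutation p = 0.001, the smallest that 1000 shuffles can give). Corrected for 3' UTR length and GC content, genes with it were higher in Paupar KD by 0.15 ± 0.01 (SE across genes) on the log2 scale. That size rests on the correction: uncorrected medians were 0.07 with the word and 0.00432 without it, and in Paupar KD replicate 1 the uncorrected median difference was -0.02. GATGCAA (828 genes) had z = -12.4 and GACAGTA (1039 genes) z = 7.40. For GACAGTA the direction itself rests on the correction: uncorrected medians were -0.02 with the word and 0.00780 without it. Between control libraries the z of GACGTA lay between -2.95 and 1.72 and that of GATGCAA between -1.87 and -0.62. The largest size of z of any word between 2 control libraries was 5.77, and over shuffled scores 5.55. Between 2 Paupar KD libraries it was 13.55, that of GATGCAA for replicates 2 and 3. So the z of GATGCAA over the comparison was smaller in size than its z between 2 libraries of the same group. Within the Paupar KD group the z of GACGTA lay between -0.49 and 0.38, and that of GACAGTA between -0.05 and 0.73. Of the 54 genes with a 3' UTR that were higher at an edgeR adjusted p under 0.10, 39 carry GACGTA or GACAGTA, 72.2% against 12.5% of all genes, and of the 35 that were lower 13 carry GATGCAA or ATTACAA, 37.1% against 14.9%. The words were picked on these same libraries, so these shares are descriptions, and over the comparison ATTACAA (z = -5.20) was smaller in size than the 5.77 between controls and the 5.55 over shuffled scores. For GATGCAA the uncorrected change over the comparison was graded by the length of the match: the median log2 fold change was -0.24 for GATGCAAA (299 genes), -0.14 for GATGCAA not followed by A (529), -0.08 for ATGCAAA without the leading G (1096), -0.04 for the core ATGCAA alone (1347) and 0.03 for genes with none (8965). In Paupar KD replicate 3 alone the medians were near 0 in each of these 5 classes, from -0.03 to 0.02. These class medians were not corrected for 3' UTR length or GC content, so how much of the gradient follows from those was not tested. Paupar KD replicate 3 also differed in the corrected scores: in pairs of 1 Paupar KD and 1 control library that share no library, the z of GATGCAA was -10.3, -15.7 and -2.30 for replicates 1 to 3, and that of ATTACAA was -1.07, -0.72 and -8.46. For ATTACAA this contrast rests on the correction: its uncorrected median differences were -0.21, -0.03 and -0.07 for replicates 1 to 3, largest in replicate 1. GTCTTCC, which pairs with the seed of the islet microRNA miR-7, had z = -6.05, little beyond the largest between controls, and is present 2 times in the Pax6 3' UTR, which holds none of the other 4 words. That 3' UTR is the longest annotated for Pax6, at 6805 bases, against 368 to 2285 bases for the called genes. Whether these cells use its full length was not tested.

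A candidate explanation of the GACGTA pattern is that a small RNA in the control KD libraries lowered genes with this word, as a microRNA lowers genes matching its seed. Genes so affected would then appear higher in Paupar KD. The labels give an ASO for each group, and whether any small RNA acting like a microRNA was added or present was not tested. The z of GACGTA was positive in each of the 3 disjoint pairs, the lowest being 7.24, which shows that no single library carries the pattern but, with the word picked on these libraries, does not bear on its cause. Base content alone is argued against: of 179 rearrangements of the same 6 bases, the highest z was 3.62, and the lowest, -6.06, was that of GATGCA, which is part of GATGCAA. GACGTA was picked for the largest z of all words, so only the size of its gap to the rearrangements bears on this. Rearrangements do not keep the neighbouring bases together, so an effect of those was not tested. A property of the whole gene, not of the 3' UTR, stays open as another candidate explanation. Genes with GACGTA in the coding sequence and not in the 3' UTR had z = 7.04. That is 50.2% of the z for the 3' UTR, between the bounds set beforehand. No untreated library was analysed, so whether an oligonucleotide of either group moved these genes was not tested, and an effect of reduced Paupar on them was not excluded.

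The wide spread among the Paupar KD libraries was not removed by equal depth: after thinning to the smallest total, their coefficient of variation was still 3.79 times that of the controls. Part of the spread may come from the oxygen or metabolic state of the cells: of 20 hypoxia-regulated genes listed before their own values were examined, 18 were tested, 4 of them members of the glycolysis list whose low median in replicate 1 was already known, and their median log2 difference from the controls was -1.30 in replicate 1 and -0.52 in replicate 2, each lower than in any of 10000 random lists of like expression, and 0.11 in replicate 3, at the 98.5th percentile of such lists. Another small RNA in replicate 3 than in replicates 1 and 2 stays open as a candidate explanation, since the values that prompted it (the z of GATGCAA of -2.30 in the pair of replicate 3, for example) do not test it. The labels give 1 treatment, an ASO against Paupar, for all 3, and how far each library's knockdown reached was not tested.

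The real split of the libraries called 6 genes and the highest of the other 9 splits called 0, so 1 of 10 splits gave as many; 10 splits are too few for a share under 0.05.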
